A study of Rattus norvegicus with 6 samples.

How the data were processed

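RNA was sequenced from 6 libraries of rat INS1 cells, 3 labelled with a control plasmid and 3 labelled with EIF2AK2 overexpression. Per the labels' protocols, total RNA was isolated with TRIzol, treated with DNase and sequenced as 150 nt paired-end reads on a NovaSeq system. The aligner TopHat2 is named in the submitters' processing notes. Its version, the genome build, the annotation release, the counting tool and the strand setting are not given in the sources used here. Without a known strand setting, overlapping and antisense genes cannot be told apart, and near-identical copies can share reads.

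The main values were the whole-number counts per gene that the authors deposited, for 19426 rat Ensembl gene rows, with no normalization. The authors also deposited FPKM values for 19409 of these genes, per the file headers. For 1633 genes with high counts, the ratio of count to FPKM differed between libraries by 1 factor, with a coefficient of variation of at most 0.0092%, so the FPKM table carries the same counts on another scale. FPKM was used only for an alternative test. Gene symbols, types and chromosomes were those in the files. The reference table of the GRCr8 assembly served only to find which genes neighbour each other, since the build of the files is not given.

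Samples were grouped by their labels. Total counts were 17321941 to 20865080 per library, and a count of 3, the limit that a count of 0 allows, corresponds to 0.144 to 0.173 CPM. Counts were tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, filterByExpr, TMM scaling, no block), libraries labelled EIF2AK2 minus libraries labelled control. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 12734 genes tested. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. CPM (counts-per-million) values use TMM-adjusted library sizes, and those in the tests of cell type use total counts. The libraries of a group differed by more than sampling noise (chi-square per degree of freedom 2.71 to 23.8), so none was treated as a duplicate.

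The 18 gene lists and 6 marker lists, the main test, the set tests and the rule for named genes were fixed before the data were examined. Each list was counted over all genes and over the list alone, and tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), with p adjusted over the 18 lists. Camera with an estimated correlation and fry were run beside it. For DESeq2, lists were tested with cameraPR (preset correlation 0.01) on its Wald statistics, not on log2 CPM. Named genes were Eif2ak2; the 10 genes with the largest increase and the 10 with the largest decrease among characterised genes that passed, had an average log2 CPM of at least 1 and did not overlap between groups; up to 4 members of each list with the smallest p; the most abundant member of each marker list; and Ins2, Bax, Bcl2, Atf4 and Ddit3. Some genes that the rule selects are not reported here, and the text says where a gene was named after its values were seen. Another 3 lists (heat shock and chaperone genes, class I antigen presentation genes and ribosomal protein genes) were added after the data were seen. Their p was adjusted over these 3 lists alone, not together with the 18 fixed lists.

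Alternatives were DESeq2 size factors in edgeR, library totals only, upper quartile scaling, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma voom, limma trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5, log2(FPKM + 1) with no filter, the replicate number as a block, each library left out in turn, Eif2ak2 left out, and thresholds of 0.01 and 0.1. Leaving out mitochondrial genes with 3 uncharacterised genes of high counts, and a robust dispersion, were added after the data were seen. On data simulated from these libraries with known changes, the edgeR step on 12630 genes recovered 46% of genes changed 1.25-fold, 74% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 9 false calls among 12494 unchanged genes. The simulation changed 50 genes at each fold, whereas 7348 of 12734 genes passed in the real data. With so few changed genes the adjusted threshold is stricter, so the simulated shares need not hold for the real test. Figures were drawn with matplotlib 3.10.9.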

Results

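Gene expression was measured by RNA sequencing in rat INS1 cells, a line derived from an insulinoma and used as a model of the pancreatic beta cell. Of 6 libraries, 3 were labelled as coming from cells given a control plasmid and 3 as coming from cells with overexpression of EIF2AK2. EIF2AK2, also called PKR, is a kinase that is activated by double-stranded RNA and phosphorylates the translation factor eIF2α. The series asked how raised EIF2AK2 affects apoptosis genes, other expressed genes and alternative splicing in beta cell damage. Splicing events were not analysed here, since the values used were per gene. The libraries labelled control held 20552177, 20048430 and 20865080 counts. Those labelled EIF2AK2 held 20218174, 20236739 and 17321941 counts. The labels number the libraries without saying that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

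Eif2ak2 (ENSRNOG00000048315, chromosome 6) was lower, not higher, in the libraries labelled EIF2AK2. Its level was 160.5 ± 4.05 CPM (counts-per-million; SD, n = 3) in the libraries labelled control and 116 ± 9.25 CPM (SD, n = 3) in those labelled EIF2AK2. The log2 fold change was -0.47 (SE 0.06, edgeR quasi-likelihood adjusted p = 4.15e-06), and each of the 3 libraries labelled EIF2AK2 lay below each of the 3 labelled control. The rat gene therefore went against the label, and every direction given here is that of the libraries labelled EIF2AK2 relative to the libraries labelled control. The species of the overexpressed sequence is not given in the sources used here, and transcripts of a construct from another species need not be counted on the rat gene.

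**Figure D1:**
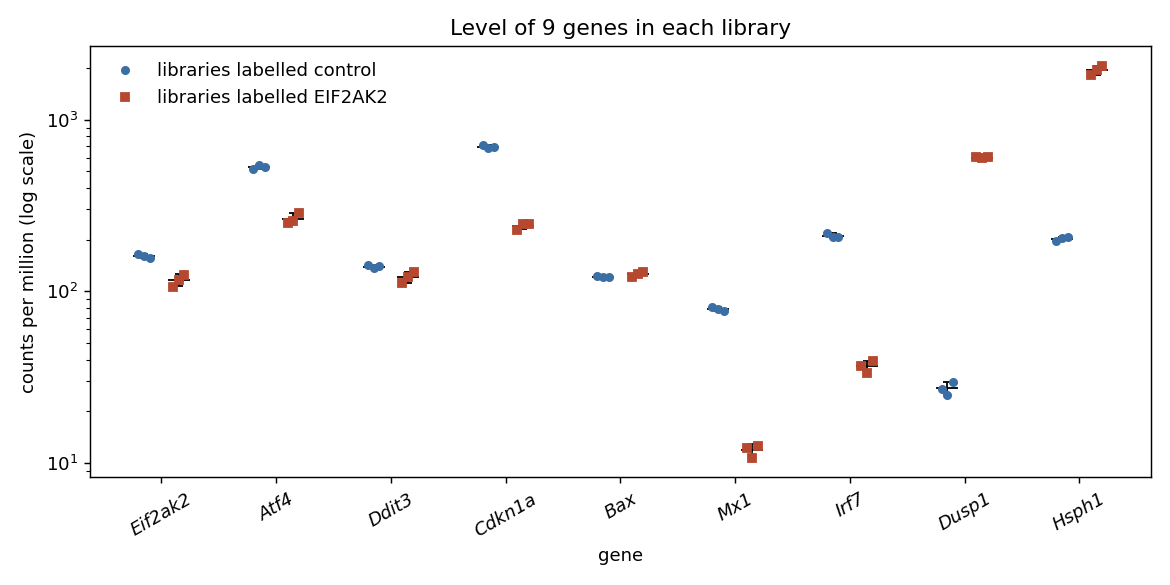
Level of 9 genes in CPM on a log axis, with 1 point per library, circles for the libraries labelled control and squares for those labelled EIF2AK2, and black marks for the mean and SD of 3 libraries. Eif2ak2 had a mean of 160.5 CPM in the libraries labelled control and 116 CPM in those labelled EIF2AK2, while Bax had means of 121.8 and 125.6 CPM.

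The 2 groups differed across much of the transcriptome. Of 12734 genes tested, 7348 (57.7%) passed an adjusted p of 0.05, with 3602 higher and 3746 lower in the libraries labelled EIF2AK2. Most of these changes were small, and 4889 of the 7348 were under 1.5-fold. At least 2-fold changes were found for 1055 genes, 661 higher and 394 lower. The CPM values of the groups did not overlap for 8108 genes (63.7%), where chance gives 10%. The first principal component held 76.1% of the variance and separated the groups. Correlations of log2 CPM across genes were 0.9941 to 0.9944 within the control label, 0.9907 to 0.9931 within the EIF2AK2 label and 0.9627 to 0.9675 between them. The balance of directions depended on scaling, with 2640 genes higher and 4897 lower with library totals only, and 4269 higher and 3176 lower with upper quartile scaling. At least 2-fold, 566 were higher and 514 lower with library totals only, and 712 higher and 355 lower with upper quartile scaling. EIF2AK2 replicate 3 stood apart on the second component and held 3.40% of its counts in a single uncharacterised gene, LOC100909555, against 1.45% to 1.81% in the other 5 libraries. Without that library 7254 genes passed, 3559 higher and 3695 lower.

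The 10 largest increases included 4 members of the immediate-early list, Dusp1 and 3 Nr4a genes. Dusp1, a phosphatase that inactivates MAP kinases, rose from 27.1 ± 2.30 to 601.4 ± 3.89 CPM (SD, n = 3 each; log2 fold change 4.47, SE 0.06, adjusted p = 6.3e-17). The orphan nuclear receptor genes Nr4a3, Nr4a2 and Nr4a1 rose by log2 fold changes of 5.40 (SE 0.15), 3.74 (SE 0.11) and 3.60 (SE 0.09). Hspa1b, an inducible HSP70 gene, rose by 5.50 (SE 0.23). It has near-identical copies that can share reads, so its value is uncertain. Gltpd2 rose by 4.72 (SE 0.18) and Hfe2 by 4.40 (SE 0.28). Hsp90aa1, which encodes the inducible HSP90 chaperone, had 3 counts in total in the libraries labelled control and 6211 in those labelled EIF2AK2, a ratio of 2350 with a 95% counting interval of 804 to 11400. Of the 3 counts, 2 were in control replicate 3, and the fitted log2 fold change was 11.03 with that library and 11.85 without it. A level this low for a chaperone gene makes it uncertain what part of the gene this row covers. A U6 small nuclear RNA row, 1 of a multicopy family, had 2 and 253 counts, a ratio of 144 with an interval of 39.4 to 1190. Both control counts were in control replicate 3, so that ratio rests on 1 library, and the fitted log2 fold change ranged from 4.73 to 9.50 over the alternatives. These intervals cover counting error only. With limma trend on log2(FPKM + 1), log2 fold changes were smaller, at 2.25 for Nr4a3, 2.64 for Nr4a2, 1.38 for Hfe2 and 5.21 for Hsp90aa1.

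The 10 largest decreases included 3 members of the interferon-stimulated list, Rtp4, Oas2 and Ifi44l. RT1-T24-3, a class I histocompatibility gene of a family whose members can share reads, fell by 3.85 on the log2 scale (SE 0.23). Ly6e fell by 3.58 (SE 0.34), with a log2 fold change of -4.31 without EIF2AK2 replicate 3. Clec2g fell by 3.48 (SE 0.23) and Mss51 by 2.96 (SE 0.21). Rtp4 had a log2 fold change of -3.25 (SE 0.17). Oas2, an antiviral oligoadenylate synthetase, fell by 2.89 (SE 0.30). Apol9a fell by 2.86 (SE 0.08), the guanylate-binding protein gene Gbp1 by 2.85 (SE 0.20) and Ifi44l by 2.74 (SE 0.18). Egr1, an immediate-early transcription factor gene, also fell, from 70.8 ± 7.70 to 10.4 ± 2.40 CPM (SD, n = 3 each). With log2(FPKM + 1), log2 fold changes were -1.85 for RT1-T24-3, -1.07 for Ly6e, -1.57 for Clec2g, -1.53 for Mss51, -0.97 for Oas2 and -1.76 for Gbp1. These too depended on the pseudocount, since none differed from the main test by more than 1.5 times with log2(FPKM + 0.1). The largest adjusted p among the 10 genes by edgeR was 9.73e-07, for Oas2.

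**Figure D2:**
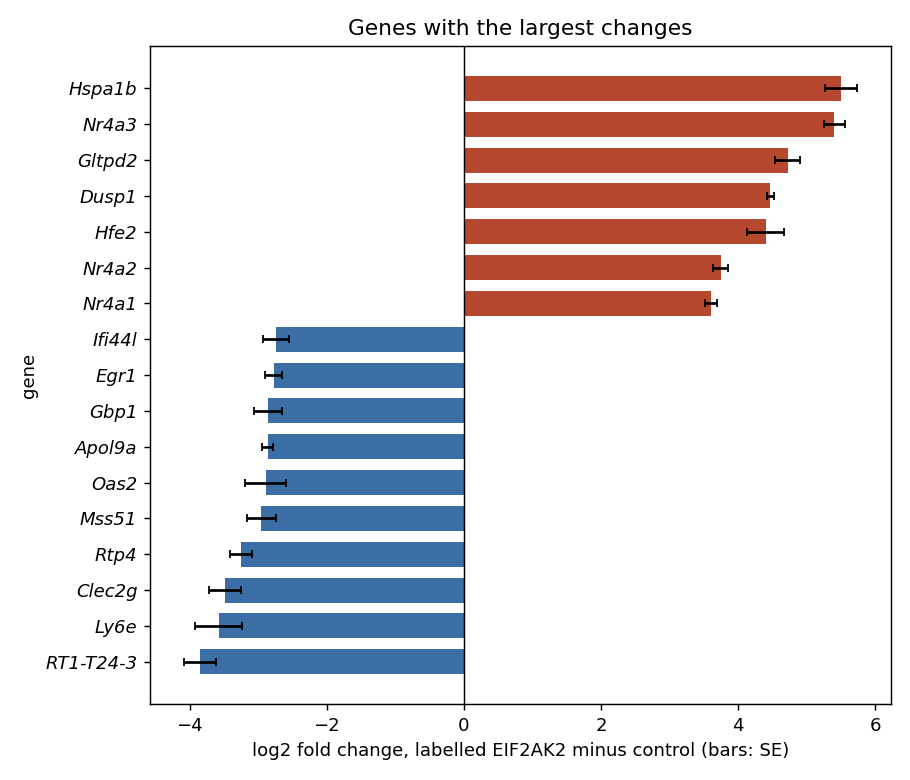
Log2 fold change of 17 of the most changed genes, libraries labelled EIF2AK2 minus control, with bars for each gene and error bars for the SE. The increases shown reach 5.50 for Hspa1b and the decreases reach -3.85 for RT1-T24-3; Hsp90aa1 and U6 are left out because the control libraries held 3 and 2 counts.

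Apoptosis genes, the subject of the series, changed in both directions. Of 32 pro-apoptotic genes tested, 7 were higher, 13 lower and 12 did not pass, and 8 and 13 passed when adjusted over the list alone. Bik, a BH3-only gene, fell from 23.9 ± 0.99 to 11.3 ± 1.71 CPM (SD, n = 3 each; log2 fold change -1.08, SE 0.10, adjusted p = 3.46e-07), and the TNF receptor gene Tnfrsf1a fell by 0.50 (SE 0.05). Bmf, another BH3-only gene, rose by 1.74 (SE 0.14), or 1.12 with log2(FPKM + 1). Bax was at 121.8 ± 1.3 and 125.6 ± 4.27 CPM (SD, n = 3 each; adjusted p = 0.43). Of 23 anti-apoptotic genes tested, 11 were higher and 7 lower, also when adjusted over the list alone. The 3 with the largest increases were Hspa1b, Bag3 at 2.69 (SE 0.07) and Hspb1 at 2.12 (SE 0.05), which encode heat shock proteins or a co-chaperone. All 3 are also in the heat shock list added later, and the mean of the anti-apoptotic list (0.543) exceeded its median (0.152). The largest decreases were Pim3 at -0.784 (SE 0.053) and Bcl2l1 at -0.774 (SE 0.058). Bcl2l1 was at 171 CPM in the libraries labelled control and 100 CPM in those labelled EIF2AK2. Pim3 and Bcl2l1 were named after their values were seen. Bcl2, near 1 CPM, had a log2 fold change of 0.18 (SE 0.31, adjusted p = 0.644). Neither list passed limma camera (adjusted p = 0.705 for the pro-apoptotic list, whose median of -0.009 and mean of 0.02 differ in sign, and 0.196 for the anti-apoptotic list). With cameraPR on DESeq2 Wald statistics, a different test, the anti-apoptotic list did pass, at an adjusted p of 0.000238. Camera with an estimated correlation gave it an adjusted p of 0.483.

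**Figure D3:**
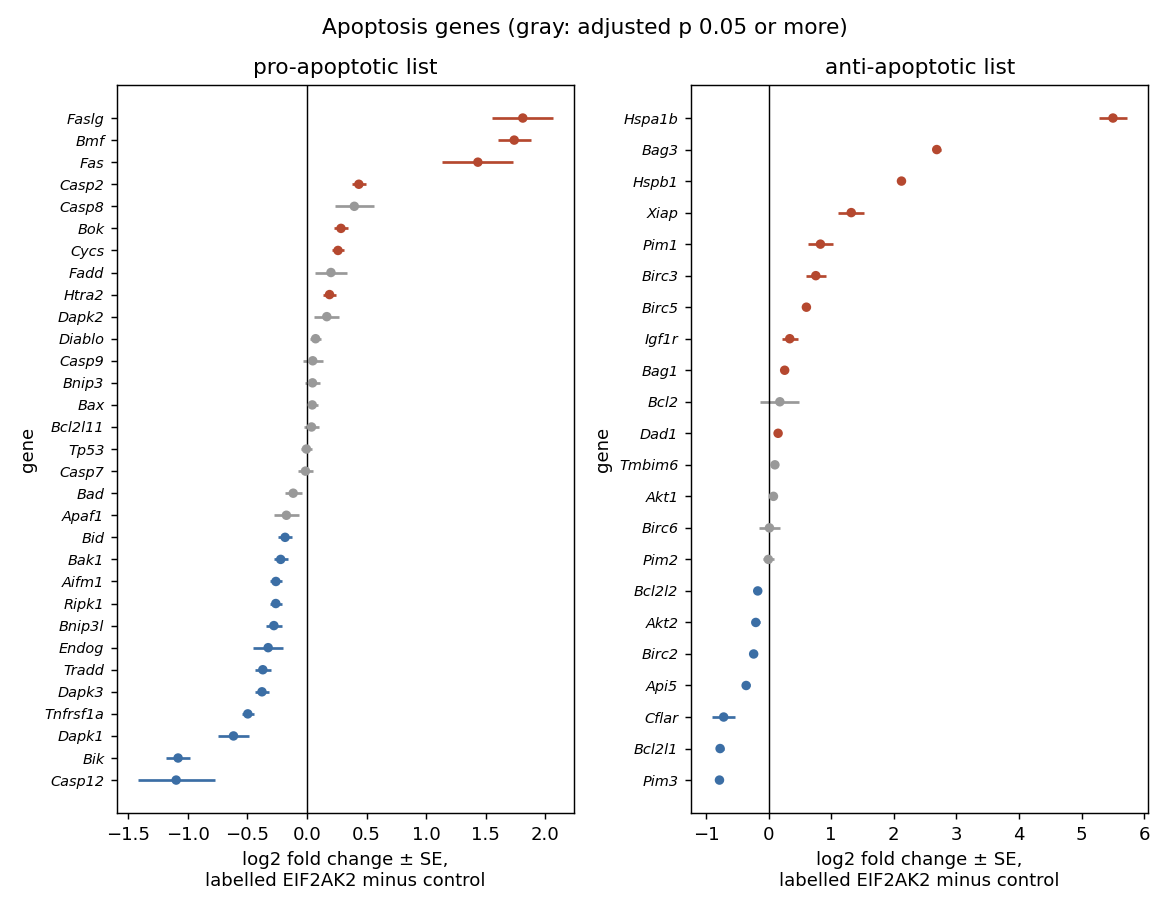
Log2 fold change with SE of 31 tested members of the pro-apoptotic list (left) and 22 of the anti-apoptotic list (right), libraries labelled EIF2AK2 minus control, with gray points at an adjusted p of 0.05 or more. Members lie on both sides of 0 in both lists, from -1.10 to 1.81 on the left and from -0.78 to 5.50 on the right.

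Several p53 target genes fell. Cdkn1a, a cyclin-dependent kinase inhibitor gene, fell from 696 ± 14.2 to 239.8 ± 10.5 CPM (SD, n = 3 each; log2 fold change -1.54, SE 0.04, adjusted p = 4.7e-13). Phlda3 fell by 1.34 (SE 0.04), Sesn2 by 0.54 (SE 0.05) and Mdm2, the p53 ubiquitin ligase gene, by 0.53 (SE 0.05). Sesn2 is also in the integrated stress response list given below. Of 21 genes tested, 6 were higher and 11 lower, also when adjusted over the list alone. The list did not pass camera (adjusted p = 0.254, and adjusted p = 0.669 with an estimated correlation). It passed in a different test, cameraPR on DESeq2 Wald statistics (adjusted p = 0.000217).

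Genes of the integrated stress response, the program downstream of eIF2α phosphorylation, were mostly lower in the libraries labelled EIF2AK2. Atf4, its central transcription factor gene, fell from 530.4 ± 12.7 to 264.9 ± 19.3 CPM (SD, n = 3 each; log2 fold change -1.002, SE 0.05, adjusted p = 3.02e-10). Gdf15 fell by 1.69 (SE 0.05), Atf5 by 0.94 (SE 0.06) and Ddit3, which encodes CHOP, by 0.21 (SE 0.05), with a log2 fold change of -0.312 with log2(FPKM + 1). Ppp1r15a, which encodes the eIF2α phosphatase subunit GADD34, rose by 0.86 (SE 0.05). Of 36 genes tested, 5 were higher and 19 lower, also when adjusted over the list alone (camera adjusted p = 0.00511, and adjusted p = 0.483 with an estimated correlation). In the list of endoplasmic reticulum chaperone and unfolded protein response genes, 20 of 29 were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.00108, and adjusted p = 0.483 with an estimated correlation). Hspa5, which encodes the chaperone BiP, fell from 1324 ± 54.2 to 888.7 ± 18.1 CPM (SD, n = 3 each). Dnajb9 fell by 0.98 (SE 0.08), Sel1l by 0.79 (SE 0.06) and Xbp1 by 0.59 (SE 0.05). Among 23 genes around the kinase itself, 6 were higher and 6 lower, also when adjusted over the list alone (camera adjusted p = 0.975). Ppp1r15b, a second eIF2α phosphatase subunit gene, fell by 1.35 (SE 0.07), and Mapk14 fell by 0.40 (SE 0.05). The median of this list was -0.012, its mean 0.002, and its direction changed with scaling.

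Interferon-stimulated genes fell together. Of 44 tested, 37 were lower and 1 was higher, or 38 and 1 when adjusted over the list alone, with a median log2 fold change of -1.20 (camera adjusted p = 2.17e-12, and adjusted p = 0.483 with an estimated correlation). The antiviral GTPase gene Mx1 fell from 78.6 ± 2.15 to 11.9 ± 1.01 CPM and Mx2 from 1057 ± 10.1 to 173.9 ± 29.4 CPM (SD, n = 3 each). Irf7, an interferon regulatory transcription factor gene, fell by 2.54 (SE 0.06) and Usp18 had a log2 fold change of -2.50 (SE 0.06). The exception was Irf1, named after its value was seen, which rose by 1.13.

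Immediate-early genes split by direction, and NF-kB genes leaned upward. Of 30 immediate-early genes, 15 were higher and 14 lower, also when adjusted over the list alone (camera adjusted p = 0.0984). Sik1, a salt-inducible kinase gene, rose by 2.95 (SE 0.05) beside Dusp1 and the Nr4a genes, while Egr1 fell. Of 28 NF-kB and inflammatory genes, 15 were higher and 6 lower, also when adjusted over the list alone (camera adjusted p = 0.0984). The NF-kB subunit gene Rel rose by 3.004 (SE 0.15), and the feedback inhibitor genes Tnfaip3 and Nfkbia rose by 2.24 (SE 0.15) and 1.55 (SE 0.04). With log2(FPKM + 1), Rel was at 1.88 and Tnfaip3 at 1.45. Cxcl10, which is also induced by interferon, fell by 0.82 (SE 0.05). With library totals only, both lists passed (camera adjusted p = 0.0195 for the immediate-early and 0.0302 for the NF-kB list). In the main test, camera with an estimated correlation gave an adjusted p of 0.483 for each.

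Cell cycle, oxidative phosphorylation and splicing factor genes were more often higher. Of 42 cell cycle genes, 33 were higher and 3 lower, or 33 and 5 when adjusted over the list alone (camera adjusted p = 2.79e-05, and adjusted p = 0.483 with an estimated correlation). Tk1 rose by 0.82 (SE 0.06), Nusap1 by 0.81 (SE 0.05), the mitotic kinase gene Aurkb by 0.74 (SE 0.06) and Cdk1 by 0.55 (SE 0.05). Of 39 nuclear genes of oxidative phosphorylation, 26 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.000305, and adjusted p = 0.483 with an estimated correlation). Uqcrfs1 rose by 0.73 (SE 0.05) and Cox7b by 0.48 (SE 0.05). Of 51 splicing factor genes, 29 were higher and 10 lower, also when adjusted over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.615 with an estimated correlation). Rbfox2 rose by 1.11 (SE 0.07) and Hnrnpl by 0.54 (SE 0.04), while Srrm2 fell by 0.69 (SE 0.04) and Snrnp70 by 0.51 (SE 0.04). Short genes leaned upward in the same libraries, with a median log2 fold change of 0.11 in the shortest quartile of genes and -0.10 in the longest.

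**Figure D4:**
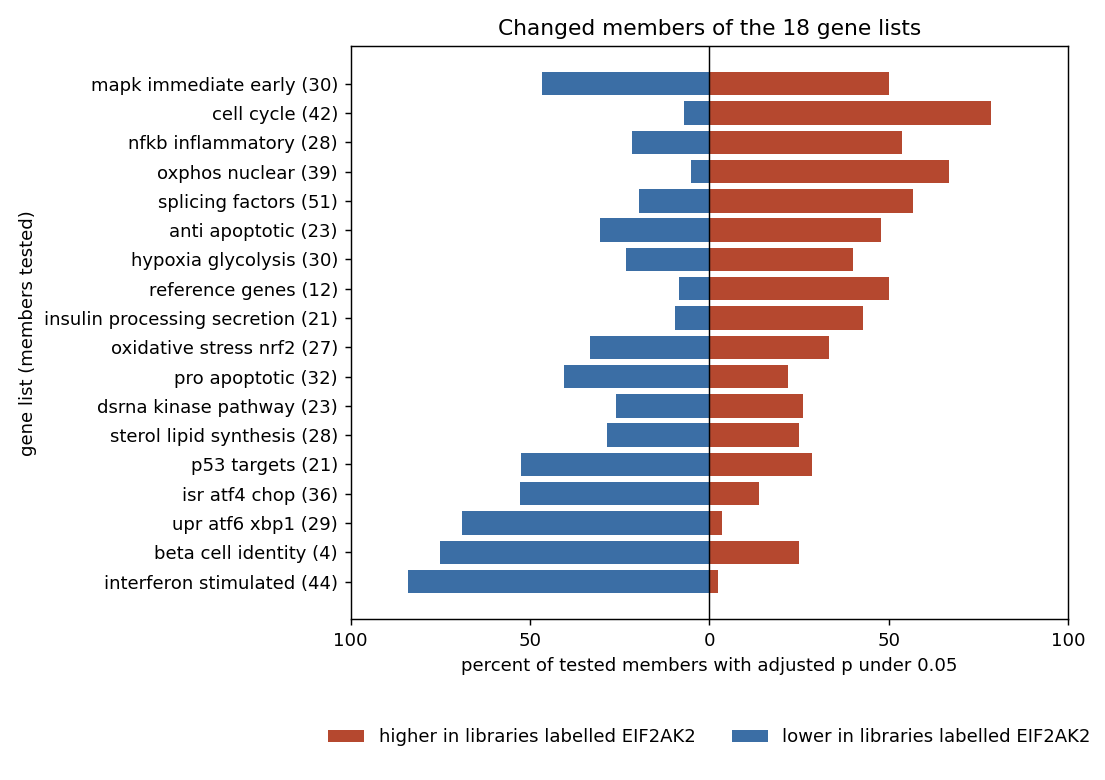
Percent of tested members of each of the 18 gene lists that were higher (right) or lower (left) in the libraries labelled EIF2AK2 at an adjusted p under 0.05, with the number tested in brackets. The interferon-stimulated list had 37 of 44 members lower, and the cell cycle list had 33 of 42 higher.

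The oxidative stress, lipid synthesis, glycolysis and reference gene lists did not pass camera. Of 27 oxidative stress genes, 9 were higher and 9 lower, or 9 and 10 when adjusted over the list alone (adjusted p = 0.862). Txnip, a thioredoxin-binding protein gene, fell from 2703 ± 208 to 909.8 ± 165 CPM (SD, n = 3 each), and Gpx1 rose by 0.53 (SE 0.04). Sterol and lipid synthesis genes had 7 higher and 8 lower of 28 (adjusted p = 0.485), with Fasn, which encodes fatty acid synthase, falling by 0.67 (SE 0.05). Hypoxia and glycolysis genes had 12 higher and 7 lower of 30 (adjusted p = 0.485), with Pkm rising by 0.40 (SE 0.04) and Pfkfb3 falling by 0.67 (SE 0.08). Both counts were the same when adjusted over the list alone. Among 12 commonly used reference genes, 6 were higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.116). Rplp0 rose by 0.45 (SE 0.05), Gapdh by 0.36 (SE 0.05) and Ppia by 0.35 (SE 0.05). Ppia lost its call with log2(FPKM + 1) and no filter (log2 fold change 0.245, adjusted p = 0.0564). The share of counts on ribosomal protein genes was 4.74% ± 0.08 in the libraries labelled control and 6.16% ± 0.18 in those labelled EIF2AK2 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows).

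Most beta cell genes with a value were close to 0 in every library. Ins2 had 2 counts among 119242541 in the 6 libraries together, or 0.0168 CPM with a 95% counting interval of 0.00203 to 0.0606. Iapp, the amylin gene, and the glucose transporter gene Slc2a2 also had 2 counts each, the prohormone convertase genes Pcsk1 and Pcsk2 had 6 and 18, Chga had 4 and Neurod1 had 1. These genes, apart from Ins2, were named after their values were seen. Ins1 had no value here. Of 29 beta cell identity genes, only 16 had a value, against 42 of 43 cell cycle and 39 of 40 oxidative phosphorylation genes. All 19426 rows stayed when rows without any count were dropped, so genes without counts may have been left out of the values. A missing value alone still does not show that a gene was absent. Of the beta cell identity genes 4 were tested, with 3 lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.485). Isl1, the one at 10 CPM or more, was at 83.8 ± 2.92 and 70.6 ± 7.99 CPM (SD, n = 3 each; log2 fold change -0.248, adjusted p = 0.00627), and had a log2 fold change of -0.155 without EIF2AK2 replicate 1 (adjusted p = 0.013). Mafa and Gipr, near 1 CPM, had adjusted p of 0.0149 and 0.0151 and lost their calls with DESeq2. Mafa also lost its call without control replicate 2 (adjusted p = 0.0554), EIF2AK2 replicate 1 (0.0541) or EIF2AK2 replicate 3 (0.0542), and Gipr without control replicate 2 (0.061) or 3 (0.0575). With log2(FPKM + 1) and no filter, their log2 fold changes were -0.396 for Mafa and -0.218 for Gipr, against -1.106 and -0.948 in the main test. Of 21 insulin processing and secretion genes tested, 9 were higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.224). Cacna1c, a calcium channel gene, rose by 0.84 (SE 0.08).

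Marker lists of other cell types were read beside these values. Of 12 fibroblast and stellate cell markers, 6 (50%) lay at 10 CPM or more, and 1 was higher and 3 lower among 9 tested. Col3a1, a fibrillar collagen gene, was at 1113 ± 29.5 and 975.4 ± 53.5 CPM (SD, n = 3 each; log2 fold change -0.191, adjusted p = 0.00239, and -0.296 with log2(FPKM + 1)). Of 12 neuronal markers, 3 lay at 10 CPM or more, with 1 higher and 1 lower among 6 tested and Nefm at 21.5 ± 3.13 and 20.9 ± 2.58 CPM. Of 9 endothelial markers, 1 did, Kdr at 122.7 ± 3.58 and 121.1 ± 8.91 CPM, and none of 3 tested passed by edgeR. Of 12 markers of other islet cell types, 1 did, Etv1 at 25.04 ± 1.36 and 26.4 ± 0.88 CPM, and it did not pass (adjusted p = 0.407). No acinar or ductal marker of 16 and no immune marker of 12 reached 10 CPM. Cel, an acinar marker, was at 4.72 ± 0.74 and 4.44 ± 1.3 CPM, with 3 higher and 0 lower among 7 acinar and ductal markers tested. Cd68, a macrophage marker, was at 1.94 ± 0.09 and 0.65 ± 0.18 CPM (log2 fold change -1.576, and -0.703 with log2(FPKM + 1)), with 0 higher and 1 lower among 2 immune markers tested.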

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

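All counts of changed genes stayed within 1.5 times of the main counts, except with FPKM. The range of genes changed was 5807 to 8151, and leaving out 1 library at a time gave 6464 to 7299 genes, or 1092 to 1151 at least 2-fold. Eif2ak2 was lower and passed under every alternative that kept its row (log2 fold change -0.57 to -0.41). With log2(FPKM + 1), 2278 genes were higher and 414 changed at least 2-fold (223 higher, 191 lower). With log2(FPKM + 0.1), 2266 were higher, 415 of them at least 2-fold, and with log2(FPKM + 1) and no filter 2324 were higher and 411 changed at least 2-fold (221 higher, 190 lower). A pseudocount of 0.1 in place of 1 moved the genes at least 2-fold from 414 to 827, and dropping the FPKM filter moved them from 414 to 411. Among named genes that passed and were tested, only Col3a1 (-0.297) and Ddit3 (-0.315) differed by more than 1.5 times with log2(FPKM + 0.1). The smaller changes given for other named genes with log2(FPKM + 1) and its filter therefore depended on the pseudocount. The unit was not varied apart from the limma trend test. The share of calls that were higher was 49.0% in the main test, 57.3% with upper quartile scaling, 35.0% with library totals only, 33.4% with log2(FPKM + 1), 33.5% with log2(FPKM + 0.1) and 35.4% without its filter. The median of all genes was -0.004 in the main test, 0.052 with upper quartile scaling, -0.099 with library totals only and -0.11 with log2(FPKM + 0.1).

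No pairing by replicate number was evident: same-numbered libraries had correlations of deviations of -0.043, 0.083 and 0.096, and not every library correlated best with its own number. Differently numbered libraries had correlations from -0.203 to 0.123. With 3 libraries in each group, whose deviations constrain each other, a pairing cannot be excluded. With the number as a block 7201 genes passed, and no named gene or list changed its call.

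None of the 18 fixed lists kept its call with an estimated correlation: adjusted p = 0.483 for the integrated stress response, unfolded protein response, interferon, cell cycle and oxidative phosphorylation lists and 0.615 for splicing factors. The shared 0.483 comes from the adjustment. Before it, camera with an estimated correlation gave p of 0.154, 0.119, 0.121, 0.241 and 0.213 for these lists in that order, and 0.363 for splicing factors. The correlation was estimated from only 6 libraries. At a threshold of 0.01 splicing factors (0.0141) were lost, and at 0.1 the NF-kB and immediate-early lists (both 0.0984) were gained. Those lists, in that order, also passed with library totals only (0.0302, 0.0195), log2(FPKM + 1) (0.0326, 0.00573), log2(FPKM + 0.1) (0.0325, 0.00793) and no FPKM filter (0.0351, 0.0399). CameraPR on DESeq2 Wald statistics gave adjusted p = 0.033 for NF-kB, 1.72e-16 for immediate-early, 0.000238 for anti-apoptotic, 0.000217 for p53 and 0.00252 for reference genes. Fry, which does not compare a list with other genes, gave 0.000808 for anti-apoptotic, p53 and NF-kB, 4.07e-05 for immediate-early, 0.00373 for insulin secretion and 0.00348 for reference genes. The cause of these changes was not tested. Of the comparisons of a named gene with an alternative, 2201 kept their side of the threshold and 11 lost the call, all of them Mafa, Gipr, Ppia (adjusted p = 0.0564) or Pgk1 (0.0652), the last 2 with log2(FPKM + 1) and no filter. No named gene that passed changed direction, while Bax, Bcl2, Cel, Etv1, Kdr and Nefm, which passed in no fit, changed sign. In simulated data, with far fewer changed genes than passed here, 74% of 1.5-fold changes were recovered. That share need not hold for the real test.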

Other observations

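Of the tests given here, those on beta cell genes, on Eif2ak2 and on heat shock genes were chosen after the result was seen; the test of neighbouring genes and the splits of the libraries were planned.

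Heat shock and chaperone genes, listed after the data were seen, were mostly higher in the libraries labelled EIF2AK2. Of 35 tested, 26 were higher and 4 lower (camera adjusted p = 5e-08, and adjusted p = 0.00921 with an estimated correlation). Adjusted p here covers only the 3 lists added after the data were seen. It is more lenient than that of the 18 fixed lists and cannot be set beside it. Since these lists were chosen after the data were seen, a small p was also likely in advance. Hsph1, an HSP110 chaperone gene, rose from 202.8 ± 4.82 to 1945 ± 121 CPM and Dnajb1, an HSP40 gene, from 140.5 ± 5.84 to 410.1 ± 12.1 CPM (SD, n = 3 each). The constitutive Hspa8 rose by 1.75, though reads shared with pseudogene copies leave it uncertain. Ribosomal protein genes were also mostly higher, 81 of 96 tested, with 4 lower (camera adjusted p = 2.59e-16, and adjusted p = 0.056 with an estimated correlation). Short genes leaned upward in these libraries, and the length trend was not removed for the ribosomal list.

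Class I antigen presentation genes fell in the same libraries. Of 24 tested, 20 were lower and 0 higher by edgeR (camera adjusted p = 1.34e-07, and adjusted p = 0.0473 with an estimated correlation). Both were adjusted only over the lists added after the data were seen. The list itself was also chosen after the data were seen. A small p was therefore likely in advance and does not set this list above the fixed ones. The transactivator gene Nlrc5 fell by 1.21 (SE 0.11; log2 fold change -0.689 with log2(FPKM + 1)), the class I gene RT1-S3 by 1.93 (SE 0.07) and the peptide transporter gene Tap1 by 0.59 (SE 0.04). Tap1, Psmb8 and Psmb9 are also in the interferon-stimulated list, and class I genes can share reads.

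Insulin and other beta cell genes near 0 are unusual for a beta cell line. Loss of reads between insulin paralogs would leave single-copy beta cell genes in place, yet the highest mean among 8 of them was 0.153 CPM, which argues against it. Another cell type met the test set for it: 50% of the fibroblast and stellate markers lay at 10 CPM or more, the bound used. Once that outcome was known, a further test was added on the abundant fibroblast genes Vim and Col1a1, of which the higher mean was 1.99 CPM, far below what fibroblasts would bring. The 2 tests point different ways, so the identity of the cells, including a line that lost its beta cell program, may be read either way and stays open.

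Eif2ak2 is itself induced by interferon, and its fall of -0.468 lay within the range of the interferon-stimulated list, of which 37 of 44 members fell (camera adjusted p = 2.17e-12, and adjusted p = 0.483 with an estimated correlation). A candidate explanation is that the rat gene moved with that list while a construct not counted on the rat gene was raised. That range is wide, so this test was easy to pass. If the labels of the 2 groups were exchanged and the construct counted, Eif2ak2 was predicted to fall more than every interferon-stimulated gene. That was not seen: 35 of 44 had a lower log2 fold change than Eif2ak2, 34 of them past the threshold. A change within the range of the list still does not decide on an exchange. With a construct not counted on the rat gene, the level of that gene would not tell the labels apart. The design has no other sample of known identity, so an exchange stays open. Whether the overexpressed protein itself lowered the rat gene was not tested.

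The rise of heat shock genes was set against 2 technical explanations. After removing the trend of fold change on gene length their median log2 fold change was 0.463, against 0.489 before, with an SD of 2.114 over the list, which by itself decides nothing. The trend was then removed from log2 CPM in each library, which moved genes by a median of 0.056. Camera with an estimated correlation gave p = 0.00312 for the list, still higher, against 0.00307 before. The list was chosen after its genes were seen to rise, and the correction was small. A p under 0.05 was therefore likely in advance and decides nothing about the cause. The list median was 0.463 after this correction, against 0.488 before, so removing the trend changed it little. Without EIF2AK2 replicate 3, the library with the most counts in a few genes, 100% of the called members passed in the same direction. Of all genes called in the main test, 92.4% also stayed called without it. The calls of this list did not rest on that library, but the same held for most called genes. A stress of transfection that differed between the groups may remain, as may an effect of the overexpressed protein, and neither was tested.

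Transcription running past strongly induced genes could raise their neighbours. The median log2 fold change of 87 tested neighbours of genes higher by at least 4-fold was 0.022, under the upper bound of 0.071 from 10000 random sets. Only 135 of the 191 induced genes (70.7%) could be placed by symbol or older symbol, so the check is void and decides nothing.

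The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 7348 changed genes and 1055 at least 2-fold, and the highest of the other splits gave 1 in both cases; the real split was the 1 that gave as many.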
